A study of Mus musculus with 2 samples.

How the data were processed

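Ventricles of WT and Fendrr KO embryos at embryonic day 12.5 were pooled by 4 per genotype, and 500 ng of total RNA was depleted of ribosomal RNA and made into strand-specific libraries with 15 PCR cycles, per the labels' protocols. Each library was read for 100 bases from 1 end on its own sequencing run. Per the labels, the WT run was begun as a paired run and stopped early, its bases were called by hand, and a filter on read length of 100 bases was possibly applied to it, while the KO run was processed by the standard pipeline. Run, base calling and genotype are therefore fully confounded.

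The deposited table gives 1 FPKM value per gene symbol and library. Reads were processed with TopHat2 2.0.6, Bowtie2 2.0.2 and Cufflinks 2.0.2 on the mouse build mm9, per the submitters' processing notes. The gene annotation and the options were not given in the sources used here. FPKM values are normalised for transcript length and mapped fragments, so the deposited FPKM totals of 367955 for WT and 335610 for KO are not depths. Of 23276 symbols, 7508 were listed at 0 in WT, 6886 in KO and 6372 in both. An exact 0 in such a table can be a failed estimate, so a gene is called listed at 0 and no fold is given against it.

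Relative depth was taken from low values, where a ratio of FPKM values of a gene is a ratio of small whole read numbers times the ratio of depths. Among 2213 genes above 0 in both libraries with a mean under 0.3 FPKM, 68.9% had a KO to WT ratio within 0.1% of 0.796 times a ratio of whole numbers up to 10. At shifted values of the step the median share was 1.17% and the highest was 10.8%. The KO library thus had 1.26 times the mapped fragments of the WT library, if the options, which were not given, kept the scaling to all mapped fragments. The absolute depths stay unknown, so that no counting interval is given.

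Ratios were computed as log2((KO + 1)/(WT + 1)) in FPKM, a scale that understates the differences of low genes, for the 11349 genes with a mean over both libraries of at least 1 FPKM. Genes at a log2 ratio of at least 1, or of -1 and below, were counted as higher or lower. No significance test of genotype is possible with 1 library per group, and no p-value was computed. Fixed before the data were examined were these rules, 44 gene lists for cell types, pathways, complexes and chromatin classes, the rule for naming genes and the alternatives. The median of each list with at least 5 measured members was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression, and a list was said to stand apart below percentile 2.5 or above 97.5. This percentile describes these libraries and is not a test of genotype. Of 44 lists, 40 had at least 5 measured members, 2 had fewer and 2 had none. About 2 of 40 independent lists are expected outside the range by chance, and genes that share regulation or that occur in several lists are not independent.

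Named genes were Fendrr and its neighbours, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 5 FPKM, leaving out small RNA symbols and unnamed loci unless among the top 3, and up to 4 members per list, of which 2 had the highest mean and 2 the furthest log2 ratio. The report does not print each gene so chosen. Other members of lists (among them Vegfa, Egln3, Slc2a3, Eno1, Pgam1, Mki67 and Uqcrc1), the copies Amd2 and Oaz1, and Kdm5d and Xist were named after their values were seen.

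Transcript lengths and GC content were medians over the transcripts of each gene in GENCODE vM21, and chromosomes and neighbouring genes came from RefSeq on GRCm38, a different build from that of the values, so no coordinates are printed. Of the expressed genes, 99.3% had a length and GC content and 99.5% a RefSeq symbol. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

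The procedure was tested on simulated data built on the levels of the 11349 genes of the WT and KO comparison. Altered genes were drawn only from those with a mean of at least 5 FPKM, so changes in lower genes were not tested. Of 100 genes altered 3-fold, 98% passed the 2-fold limit, as did 100% of 100 genes altered 4-fold and 0% of 11089 unaltered genes. The simulated scatter was that of the central genes, the same at every level and without counting noise. The share of unaltered genes is therefore no rate of false calls for these libraries. Of 40 unshifted lists, 2 fell outside the range, and 10 of 10 lists shifted by 0.3 were found above it. The shifted lists were drawn only from the larger lists, so whether a shift of a small list would be found was not tested.

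Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5, 5 other scalings (median centring, upper quartile, trimmed mean with 30% of log ratios and 5% of levels trimmed from each end, quantile normalization, and equal totals after leaving out haemoglobin genes, mitochondrially encoded genes, which had no row under the symbols searched, and the 50 most abundant genes), size limits of 1.5-fold and 4-fold, list means, and random lists without matching. Chosen after seeing the data were counts without transcripts under 200 nt and random lists matched on expression, length and GC content.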

Results

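The transcriptome of the embryonic heart ventricle was measured in wild-type (WT) mice and in mice lacking both copies of Fendrr, a long non-coding RNA gene that lies next to the transcription factor gene Foxf1. Embryos were taken at embryonic day 12.5 and had been made by tetraploid complementation, in which the embryo proper derives from the embryonic stem cells that are combined with a tetraploid host. RNA of 4 pooled ventricles per genotype gave 1 strand-specific library of ribosomal RNA-depleted total RNA for each genotype. The 2 libraries were sequenced on separate runs, so that genotype and run cannot be told apart in any value below. With 1 library per genotype, no difference has a replicate check, and "higher" and "lower" compare these libraries only. Values were given for 23276 genes in FPKM (fragments scaled to transcript length and to all mapped fragments), and 11349 of them had a mean of at least 1 FPKM. Total depth is unknown. If values were scaled to all mapped fragments, the ratios of low values put the depth of the KO library at 1.26 times that of the WT library.

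The targeted gene gave no check of the genotype labels. Fendrr had no row under that name, and the row under its older symbol 1110050K14Rik was listed at 0 in both libraries. Its neighbour Foxf1, a forkhead factor of lung and gut mesenchyme, was listed at 0.0315 FPKM in WT and 2.46 FPKM in KO, a log2 ratio of 1.74 on the log2(FPKM + 1) scale. The FPKM ratio was 78.0, which equalled 98.0 KO reads for each WT read before scaling between the libraries. The WT value lies near 0, where the size of a fold is uncertain. Afp and some other genes of liver and yolk sac were also higher in KO, as given below. From which tissue the Foxf1 reads came was not tested. The other forkhead genes of the cluster did not share this difference: Foxc2 was at 1.88 FPKM in WT and 1.65 FPKM in KO, and Foxl1 at 0.155 and 0.123 FPKM. Mthfsd, which lies between Foxf1 and Foxc2, was at 5.94 and 5.53 FPKM, and the more distant genes Irf8 (0.811 and 0.817 FPKM) and Map1lc3b (35.8 and 33.4 FPKM) also had similar values in the libraries. The 8 measured genes of this neighbourhood had a median at percentile 35.0 among random lists of matched expression. With a pseudocount of 5 the log2 ratio of Foxf1 was 0.57, which is under the 2-fold limit.

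The comparison of KO with WT asks which genes differ in the ventricle without Fendrr. Few genes were far apart: 53 were at least 2-fold higher and 44 at least 2-fold lower in the KO library, and 99.1% of the expressed genes lay within 2-fold on the log2(FPKM + 1) scale. Of the 53 higher genes, 20 had transcripts under 200 nt, against 2 of the 44 lower genes. The median log2 ratio of all expressed genes was -0.11, with 95% of genes between -0.64 and 0.49, and list medians are therefore given relative to this median. Bringing the median to 0 gave 66 higher and 27 lower genes, so that the share of higher genes was 71.0% in place of 54.6%.

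**Figure D1:**
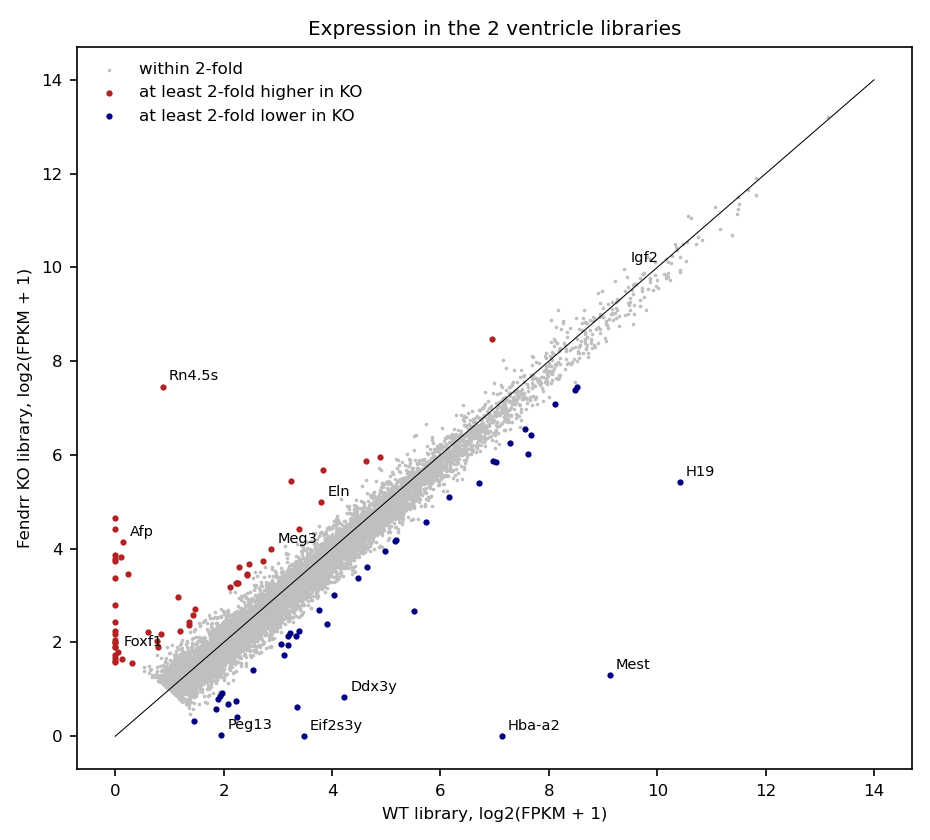
Expression of the 11349 genes with a mean of at least 1 FPKM in the WT library (x axis) and the Fendrr KO library (y axis), both as log2(FPKM + 1), with 1 point per gene, equal values on the line and genes at least 2-fold apart on this scale in colour. Most genes lie along the line, while Mest and H19 lie far below it and Afp and Foxf1 lie near 0 in WT.

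Several imprinted and Y-linked transcripts were among those furthest below their WT level. Mest, a paternally expressed imprinted gene of the mesoderm, was at 557 FPKM in WT and 1.48 FPKM in KO, a log2 ratio of -7.81. H19, the maternally expressed non-coding RNA of the Igf2 locus, was at 1360 FPKM in WT and 41.9 FPKM in KO (log2 ratio -4.99). Peg13, a paternally expressed non-coding RNA, was at 2.86 FPKM in WT and 0.0129 FPKM in KO. Igf2, a growth factor expressed from the paternal copy, was higher in KO, at 1004 against 671 FPKM. Meg3, a maternally expressed non-coding RNA, was at 6.38 FPKM in WT and 15.0 FPKM in KO, and Rian, from the same cluster, at 27.2 and 42.3 FPKM. The paternally expressed list (19 measured genes) had a median 0.19 above that of all genes, at percentile 99.79, although it holds Mest and Peg13. By its mean, which those genes dominate, the same list lay at percentile 0.48, and with quantile normalization its median lay at 95.995, inside the range. The maternally expressed list (18 genes) lay at percentile 65.7.

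Transcripts of the Y chromosome were at low levels in the KO library. Ddx3y was at 17.7 FPKM in WT and 0.786 FPKM in KO, and Uty at 9.24 and 0.535 FPKM. Eif2s3y was at 10.1 FPKM in WT and listed at 0 in KO, as was Kdm5d, at 0.307 FPKM in WT. Xist, the RNA that coats the inactive X chromosome of females, was low in both libraries, at 0.0454 FPKM in WT and 0.0677 FPKM in KO.

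**Figure D2:**
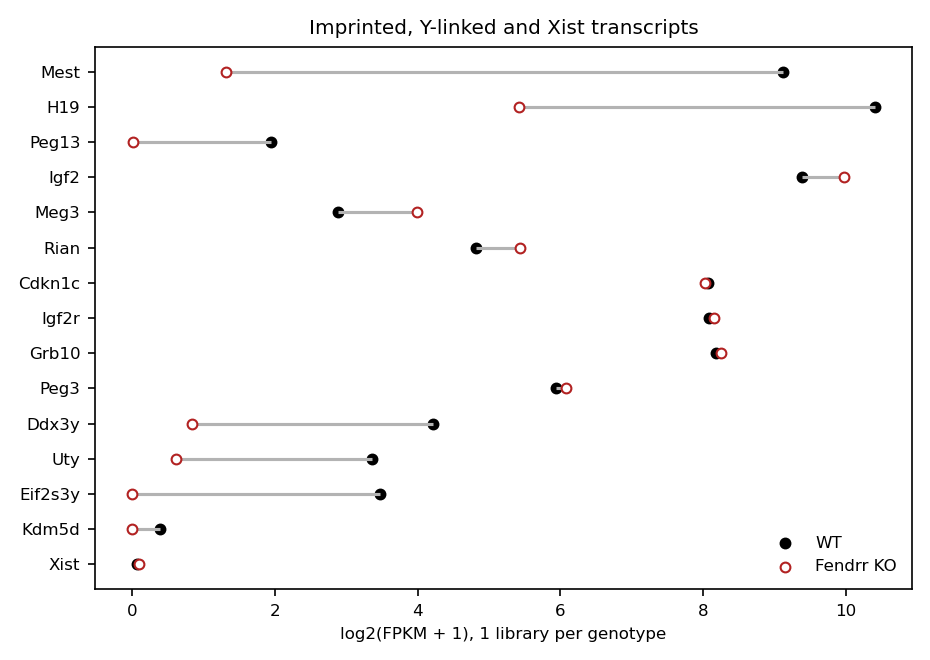
Levels of imprinted genes, Y-linked genes and Xist as log2(FPKM + 1) in the WT library (filled points) and the Fendrr KO library (open points), with 1 library per genotype and no error. Mest, H19, Peg13 and the Y-linked genes are lower in KO, while Grb10, Igf2r, Cdkn1c and Peg3 have similar values in both libraries.

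Genes of the extracellular matrix were higher in the KO library. Of 33 measured genes of cushion mesenchyme and fibroblasts, 31 lay above the median of all genes, and the list's median was 0.37 above it, at percentile 100 of the random lists. Eln, which encodes the elastic fibre protein elastin, was at 12.9 FPKM in WT and 31.0 FPKM in KO. Dpt, which encodes dermatopontin, was at 4.95 and 10.4 FPKM, Postn (periostin) at 163 and 224 FPKM and Sparc at 362 and 481 FPKM. Outside the list, the matricellular gene Sparcl1 was at 23.7 FPKM in WT and 57.5 FPKM in KO. On the log2(FPKM + 1) scale of the deposited values 1 of the 33 genes, Eln, was at least 2-fold higher. With a pseudocount of 0.1, or under each of the 5 other scalings, 2 were, Dpt being the other. The basement membrane list (15 genes) was within the range of random lists, at percentile 89.4.

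Genes of hypoxia and glycolysis were higher as a list, with 22 of 29 above the median of all genes, a median 0.39 above it and percentile 100. The higher members included the angiogenic factor Vegfa (18.4 FPKM in WT and 29.1 FPKM in KO), Ndrg1 (2.30 and 5.01 FPKM), the oxygen-sensing hydroxylase Egln3 (4.08 and 6.86 FPKM) and the glucose transporter Slc2a3 (8.03 and 12.9 FPKM). Several abundant glycolytic enzymes were lower in KO, among them Eno1 (313 and 226 FPKM) and Pgam1 (235 and 163 FPKM), while Gapdh was at 1286 and 1445 FPKM. No gene of this list was 2-fold apart on the log2(FPKM + 1) scale, and 2 (Ndrg1 and Aldoc) were at least 2-fold higher with a pseudocount of 0.1.

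Proliferation genes were lower in the KO library. Of 57 replication-dependent histone genes, 52 lay below the median of all genes, and the median was -0.45 relative to all genes, at percentile 0.00. As deposited, 8 of them were at least 2-fold lower in KO, against 1 under each of the 5 other scalings and 4 with a pseudocount of 5. Hist4h4 was at 13.9 FPKM in WT and 4.25 FPKM in KO and Hist1h4c at 124 and 57.3 FPKM, while Hist2h2bb was higher, at 933 and 1162 FPKM. Histone genes have near-identical copies, so that the level of a single copy is uncertain. The 13 H4 genes together summed to 2563 FPKM in WT and 1411 FPKM in KO. Of 42 cell cycle genes, 35 lay below the median of all genes, with a list median of -0.16 relative to it and percentile 0.19. Pcna, the replication clamp, was at 177 FPKM in WT and 120 FPKM in KO, the mitotic kinase Plk1 at 16.6 and 10.2 FPKM, and Mki67 at 45.1 and 43.3 FPKM. No cell cycle gene was 2-fold apart on the log2(FPKM + 1) scale.

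Nuclear genes of oxidative phosphorylation were also lower as a list, with 39 of 57 below the median of all genes, a median of -0.15 relative to it and percentile 1.16. Atp5b was at 968 FPKM in WT and 735 FPKM in KO, and Uqcrc1 at 144 and 91.3 FPKM. Atp5k went the other way, at 124 FPKM in WT and 355 FPKM in KO, as did Cox8b, at 17.1 and 32.3 FPKM. By its mean this list lay at percentile 39.37, and with quantile normalization at 4.24, both inside the range of random lists.

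Among the other cell types, the endothelial and endocardial list was above the range, with 22 of 31 genes above the median of all genes, a median 0.14 above it and percentile 99.23. The VEGF receptor gene Flt1 was at 5.45 FPKM in WT and 8.33 FPKM in KO, and Erg at 10.7 and 15.3 FPKM, while Emcn was at 50.1 and 41.0 FPKM. The erythroid list (19 genes) was below the range, with a median of -0.18 relative to all genes and percentile 0.72. With a pseudocount of 5 the erythroid list lay at percentile 19.96, and at a minimum mean of 5 FPKM at 3.21, both inside the range. Hba-a2 was at 139 FPKM in WT and listed at 0 in KO, and its near-identical copy Hba-a1 at 1583 and 2122 FPKM, so that their separate levels are uncertain and their sum was 1722 FPKM in WT and 2122 FPKM in KO. Leukocyte and platelet genes (17) lay at percentile 96.7 with members on both sides: Ctss (4.51 and 11.8 FPKM) and C1qb (1.58 and 4.41 FPKM) were at least 2-fold higher in KO and Ppbp (3.25 and 0.619 FPKM) at least 2-fold lower, while the macrophage genes C1qc (2.32 and 2.13 FPKM) and Cd68 (1.44 and 1.03 FPKM) did not share the higher values. Epicardial genes (15) lay at percentile 39.2 and genes of neural crest and nerve (5) at percentile 8.88. Of the liver, lung and skeletal muscle markers, 2 reached a mean of 1 FPKM, both of them liver and yolk sac genes: Afp at 0.110 FPKM in WT and 16.6 FPKM in KO, and Ttr at 0.438 and 1.79 FPKM.

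Some signalling and patterning lists were also above the range. Wnt pathway genes (19) had a median 0.21 above that of all genes, at percentile 99.69, with the secreted modulator Sfrp2 at 7.79 FPKM in WT and 15.7 FPKM in KO and the ligand gene Wnt2 lower, at 1.55 and 0.633 FPKM. Genes of the BMP and TGF-beta pathway (27) were 0.16 above, at percentile 99.76, with the target gene Id1 at 9.73 and 15.9 FPKM and Smad4 at 24.3 and 16.3 FPKM. By the mean the BMP and TGF-beta list lay at percentile 97.18, inside the range. Developmental transcription factors known as Polycomb targets (14 measured, Foxf1 included) were 0.31 above, at percentile 99.90, with Hand1 at 4.35 FPKM in WT and 6.86 FPKM in KO and Prrx2 lower, at 9.07 and 4.90 FPKM. Without a filter on low values this list lay at percentile 91.68. The Notch (15 genes), hedgehog (9) and retinoic acid (12) lists lay at percentiles 94.1, 94.3 and 38.2, and the hedgehog list, Foxf1 included, was above the range under 4 alternatives. Polycomb group genes (26) lay at percentile 19.8, and trithorax and MLL group genes (20) at percentile 11.1. None of the 39 Hox genes with a row reached a mean of 1 FPKM.

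**Figure D3:**
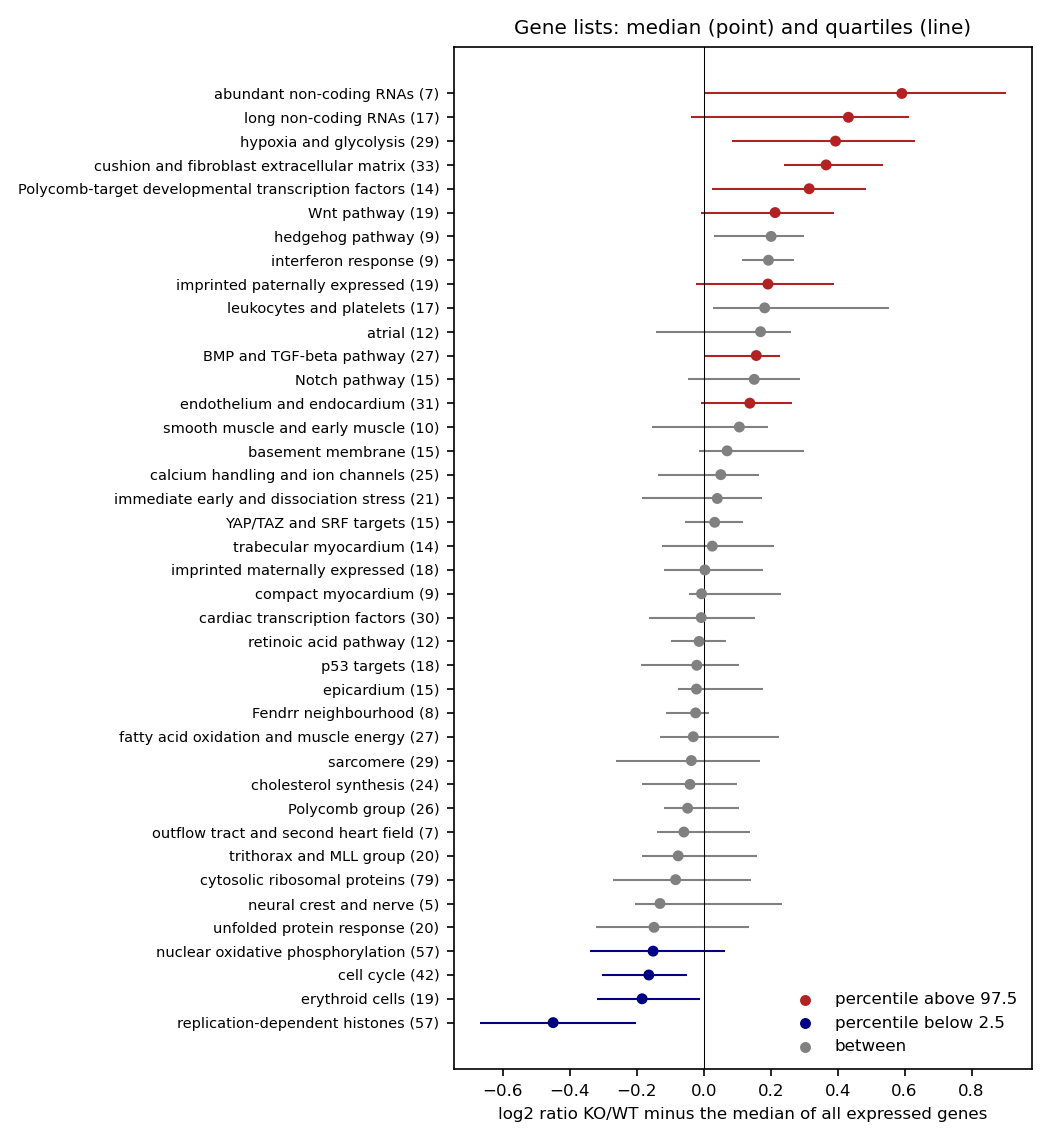
Median (points) and quartiles (lines) of the log2 ratio of KO to WT in each gene list with at least 5 measured genes, relative to the median of all expressed genes, with the number of measured genes in parentheses and colour for lists outside the central 95% of matched random lists. Of these lists, 9 lie above the range and 4 below it, and the replication-dependent histones lie lowest.

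The contractile and transcription factor programmes of the cardiomyocyte did not stand apart. Cardiac transcription factors (30 genes) lay at percentile 51.8 and had no member 2-fold apart, with Myocd, a coactivator of muscle genes, at 10.8 FPKM in WT and 6.36 FPKM in KO. Sarcomere genes (29) lay at percentile 58.1: the ventricular light chain Myl2 was at 9103 FPKM in WT and 9478 FPKM in KO, and Tnni3, the adult cardiac troponin I gene, at 753 and 443 FPKM. Genes of calcium handling and ion channels (25) lay at percentile 86.8, with the calcium store protein gene Casq2 at 51.9 and 100.3 FPKM. The trabecular (14), compact (9) and atrial (12) lists lay at percentiles 64.6, 57.3 and 96.55, the smooth and early muscle list (10) at 91.7, and the outflow tract and second heart field list (7) at 24.1. Lists of fatty acid oxidation and muscle energy (27), cholesterol synthesis (24), cytosolic ribosomal proteins (79), immediate early and dissociation stress genes (21), YAP/TAZ and SRF targets (15), p53 targets (18) and interferon response (9) lay at percentiles 49.6, 29.1, 28.7, 65.85, 76.2, 35.7 and 93.4. The unfolded protein response (20) lay at percentile 2.83, near the lower limit. The mitochondrially encoded genes of the fixed list had no row under the symbols searched and were not analysed here.

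Both non-coding RNA lists had medians above the range, with members on both sides. The long non-coding RNA list (17 genes) had a median 0.43 above that of all genes, at percentile 100, with Malat1 at 306 FPKM in WT and 451 FPKM in KO and Snhg6 at 9.20 and 16.1 FPKM. By its mean, which H19 dominates, this list lay at percentile 85.42. Meg3, Rian, Mirg, Airn and H19 are also in an imprinted list. The list of abundant non-coding RNAs (7) lay at percentile 99.99, although its most abundant members Rmrp (2889 and 2425 FPKM) and Rpph1 (1178 and 947 FPKM) were lower in KO. Of all transcripts with a length under 100 nt, 22 had a value above 0, all of them in the KO library, and all 22 were listed at 0 in the WT library. Among the genes furthest apart at any length, Rn4.5s, which is not one of these 22, was at 0.834 FPKM in WT and 174.9 FPKM in KO. AF357355 and Gm20594 were listed at 0 in WT, with 20.6 and 24.2 FPKM in KO.

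Of the remaining genes furthest apart, Lars2, a mitochondrial leucyl-tRNA synthetase gene, was at 13.2 FPKM in WT and 50.5 FPKM in KO, and Cox4i2 at 3.89 and 11.3 FPKM. Bok (7.68 and 2.34 FPKM), Tagln3 (8.08 and 2.88 FPKM) and Lrwd1 (9.15 and 3.43 FPKM) were lower in KO. Amd1 was at 0.170 FPKM in WT and 10.1 FPKM in KO, but its near-identical copy Amd2 was at 43.0 and 23.5 FPKM, and their sum was 43.2 FPKM in WT and 33.6 FPKM in KO. Oaz1-ps, a pseudogene, was at 44.7 and 5.40 FPKM beside 55.0 and 55.9 FPKM for Oaz1. Both pairs are uncertain for the reason given for the globin copies.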

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

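No paired analysis was possible because each genotype has 1 library. For the same reason no library could be left out. Counts of higher and lower genes were 98 and 98 with a pseudocount of 0.1, 16 and 17 with a pseudocount of 5, 175 and 408 at 1.5-fold, and 17 and 7 at 4-fold, against 53 and 44. A minimum mean of 5 FPKM gave 26 higher genes, and leaving out transcripts under 200 nt, chosen after seeing the data, gave 33. Lower genes numbered 27 with median centring, upper-quartile and trimmed-mean scaling, 26 with quantile normalization and 25 with equal totals after leaving out abundant genes, where higher genes were 68 and the share of higher genes 73.1%. The median log2 ratio was -0.13 with a pseudocount of 0.1, -0.069 with a pseudocount of 5, -0.051 without a filter and -0.13 at a minimum mean of 5. By construction it was 0 with median centring, and it was 0.0025 with upper-quartile scaling, -0.00037 with the trimmed mean, -0.0068 with quantile normalization and 0.017 with equal totals. Of the 13 lists outside the range, 7 stayed outside it on their side under every alternative in which they were ranked. In the other direction, 8 lists within the range left it in 14 cases. Above it were hedgehog at percentile 97.925 (pseudocount 5), 97.56 (quantile normalization), 98.78 (list mean) and 97.745 (unmatched), interferon response at 99.58 (no filter), 98.205 (quantile normalization) and 97.65 (equal totals), atrial genes at 98.71 (equal totals) and 97.61 (unmatched), fatty acid oxidation at 99.50 (no filter), leukocytes at 99.18 (unmatched) and Notch at 97.55 with length and GC matching, chosen after seeing the data. Below it without matching were ribosomal proteins at 0.695 and the unfolded protein response at 1.13. The paternally expressed imprinted list moved from percentile 99.79 to 0.48 when the mean replaced the median, since a mean takes in the values of Mest and Peg13, and the long non-coding RNA list to 85.42, since its mean takes in H19. For the other moved values, except where the construction of the setting gives it, the cause was not tested. Of 172 named genes, 26 crossed the 2-fold limit under at least 1 alternative, and no gene beyond it changed sign. Summing rows of a symbol altered nothing, since 0 symbols had several rows. The unknown absolute depth limits what can be said of genes near 1 FPKM.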

Other observations

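All tests in this part were chosen after the result was seen. No autosome had a shift near that of an extra copy in all cells, where 3 copies in place of 2 would give about 0.58. Relative to the median of all genes, autosome medians of the log2 ratio ran from -0.049 on chromosome 8 to 0.027 on chromosome 1. The next lowest was chromosome 16, at -0.025. No spread of these medians was computed, so smaller shifts, such as that of chromosome 8, stay open. The X chromosome was at 0.052. Metallothionein genes, which bind zinc and copper, were higher in KO: Mt1 was at 9.45 FPKM in WT and 20.5 FPKM in KO, and Mt2 at 1.24 and 6.89 FPKM. Of the liver genes in the fixed list with a mean under 1 FPKM, Apob was at 0.137 FPKM in WT and 1.12 FPKM in KO, Ahsg at 0.311 and 1.20 FPKM and Apoa2 at 0.147 and 0.350 FPKM. Apoa1 was listed at 0 in WT and 1.67 FPKM in KO, and Alb was listed at 0 in both. The genes named in this paragraph were chosen after their values were seen. Near Mest, Cpa4 had the highest log2 ratio of the 10 nearest expressed genes, at 0.704 FPKM in WT and 3.10 FPKM in KO, while Copg2, of the maternally expressed list, was at 31.3 and 28.3 FPKM.

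The first pattern is that short RNAs were higher in the KO library. Of 22 RNAs under 100 nt with a value above 0 in either library, 0% had a WT value above 0. It follows that 0 were seen in the WT library only, against 22 in the KO library only. Counting noise, or a lower depth of the WT library, would leave a good part of them in WT only, so the tables argue against it. A listed 0 can also be a failed estimate, which was not told apart from absence here. A minimum read length applied to the WT run, which the labels name as possible, may account for the RNAs under 100 nt. RNAs from 100 to 200 nt are long enough for a full read but were also more often higher in KO, since of 38 detected 14 were seen in KO only and 4 in WT only, and 9 were at least 2-fold higher and 2 at least 2-fold lower, so this part stays open. An effect of the Fendrr deletion on short RNAs stays open and untested, since the run and the genotype are confounded.

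The next pattern is that Mest, H19, Peg13 and the Y-linked genes were far lower in the KO library, where H19 was still at 41.9 FPKM. The 10 nearest expressed genes had median log2 ratios of -0.037 at Mest, -0.060 at H19 and -0.17 at Peg13. These values argue against loss of a chromosome segment reaching the neighbours. Of 34 other measured genes of the fixed imprinted lists, 1 (2.94%) was at least 2-fold apart, and it was higher in KO. None of them was 2-fold lower, the lowest log2 ratio being -0.56, so a large loss of expression did not extend to them. These lists leave out Cpa4, near Mest, which was past the limit at 0.704 FPKM in WT and 3.10 FPKM in KO. Erasure of imprinting at all loci is not decided by the count of list genes. A change from 1 to 2 active copies stays under the 2-fold limit on the log2(FPKM + 1) scale. Xist at 0.0677 FPKM in KO argues against KO embryos with 2 X chromosomes, 1 of them inactivated, as the reason for the low Y-linked transcripts. A difference between the embryonic stem cell clones other than the Fendrr deletion, such as loss of the Y chromosome or altered imprints in culture, may account for the pattern, and it cannot be told apart from an effect of the deletion with 1 library per genotype. Independent clones of each genotype would be needed.

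The last pattern is that the matrix and hypoxia lists lay above and the cell cycle and histone lists below the random lists. When random lists were also matched on length and GC content, in broad classes, 4 of the 4 lists stayed outside the range. This argues against GC content or transcript length bias between those classes as the reason. Bias within a class was not tested. A lower share of cardiomyocytes alone would raise the lists of other cell types alike. The matrix and erythroid medians differed by 0.55, with a resampled 95% range from 0.39 to 0.71 over genes. They were picked as the highest and lowest lists, so this is not the range of a pair fixed in advance. The erythroid call was also lost with a pseudocount of 5 and at a minimum mean of 5 FPKM. The matrix and epicardial medians differed by 0.39 (0.18 to 0.54). These lists did not move alike, but each cell type can vary on its own, so a lower share of cardiomyocytes is not decided. The sarcomere and cardiac transcription factor lists lay inside the range. More matrix-producing mesenchyme, a difference in stage or oxygen supply, another effect of the run and an effect of the Fendrr deletion were not tested and stay open.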
